A study of Mus musculus with 8 samples.

How the data were processed

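Polyadenylated RNA of 8 mouse retina samples was sequenced, 4 labelled PD-L1 knockout and 4 labelled control, all named for choroidal neovascularization. Per the labels' protocols, total RNA was isolated with TRIzol and libraries were made with a VAHTS Universal V6 kit. Per the submitters' processing notes, the tools were fastp, HISAT2 and HTSeq and the build was mm10. Their versions, the gene annotation, the strand setting of the counting and any filters are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The deposited count table, made by the authors, holds whole read counts per gene for 25477 genes, not normalized, with no row that names no gene. The deposited FPKM table, made by the authors, holds counts scaled to gene length and library total. Each FPKM value equals the count divided by the library total and by 1 fixed length per gene, with a largest deviation of 2.9e-11%. Samples were matched to columns by title, and no column was left unassigned. Libraries are called knockout 1 to 4 and control 1 to 4 after the numbers in their titles. The check that the numbers pair the libraries across groups is given with the alternatives.

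Counts were analysed with edgeR 4.0.16 in R 4.3.3. Library sizes were scaled by TMM factors, genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 16861 genes, and a quasi-likelihood model without robust dispersions compared knockout with control, with no covariate. P-values are two-sided and adjusted by Benjamini and Hochberg over all genes tested, with a threshold of 0.05. A fold change is the knockout over the control, so that a positive log2 value means higher in the knockout. Its standard error (SE) is the absolute log2 fold change divided by the square root of the F statistic of the test. The SE thus restates the test and is rough for genes of few counts. CPM are counts scaled to the TMM-adjusted library size by edgeR, given as mean ± SD over 4 libraries. The Cd274 level was also compared by an exact permutation test. Principal components were taken from log2 CPM of the tested genes with a prior count of 2. With 31743404 to 36438248 counts per library, 1 count is 0.028 to 0.0314 CPM, and levels under 1 CPM rest on few reads. Intervals and spreads do not cover PCR duplicates, which counts without molecular identifiers cannot show.

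Gene lists were fixed before the data were examined: 37 lists, of which 607 of the 618 entries matched a gene of the table. The sex-linked list is given only per library, as it is not part of the test. Lists with at least 5 tested genes (34 lists) were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the 34 lists, and again with a correlation estimated per list and with fry. The lists of T, NK and B lymphocytes and of neutrophils were too small. Members were also counted after adjustment of their p-values over the list alone. The genes named in the text follow a rule fixed at the same time. It takes first Cd274, Pdcd1lg2, Pdcd1, Vegfa, Aif1, Mapk3, Dusp6, Gfap, Ccl2, Il1b, Tnf and Il6. It adds the 10 largest increases and the 10 largest decreases among genes past the threshold whose groups do not overlap and whose mean reaches 1 CPM in a group, with predicted genes (3 among the increases, 5 among the decreases) replaced by the next named gene. From each list it takes up to 4 members past the threshold with the smallest p, or the 2 with the smallest p as values where none pass. Some genes that the rule takes are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

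Positions are those of the RefSeq annotation of the mouse assembly GRCm38.p6, matched by Entrez identifier for 24629 genes (96.7%). GC content was taken from the longest transcript of each gene in the GENCODE annotation of that assembly. Enrichment of Gene Ontology and KEGG terms, as annotated in the deposited table, used terms with 10 to 500 tested genes, a one-sided hypergeometric test, the annotated tested genes as background and adjustment over all terms of a source. It was chosen after the gene changes had been seen.

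The alternatives fixed beforehand were RLE size factors, upper quartile scaling, library size only, no filter on low counts, a stricter filter (1 CPM in at least 4 libraries), robust dispersions, DESeq2 1.42.0, limma-voom with and without sample quality weights, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), each library left out, the title number as a block, protein-coding genes only, a test against a fold of 1.2 (glmTreat), and leaving out genes within 20 Mb of Cd274. After seeing the data, 5 more were added: leaving out the 3 libraries whose lens list summed to over 100 CPM, the log2 lens sum as a covariate, a correction of each library's trend with GC content and gene length (splines with 5 degrees of freedom), that correction with the block, and scaling without mitochondrially encoded genes. No pair of libraries in a group matched within sampling noise, with chi-square values per degree of freedom of 20.3 to 108, so all 8 counted as separate samples.

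The scripts were tested on simulated counts for this comparison: 16861 genes with 200 changed, of which 16639 passed the filter. Of the genes changed by a fold of 1.5, 2 and 4, the test recovered 46.3% (31 of 67), 79.1% (53 of 67) and 98.5% (65 of 66), and 9 of 165 calls (5.45%) were false. The other 7 calls were genes of a list of 20 raised by a fold of 1.5 besides the 200. That list was called with either correlation and 0 of 34 random lists were. The genes were simulated independently of each other, so this does not show how the preset correlation serves genes that move together. A planted term was called and 0 of 300 random terms were. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.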

Results

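Messenger RNA was measured in 8 retina samples from mice with choroidal neovascularization (CNV), a model in which new vessels grow from the choroid under the retina. In 4 of them the labels give the genotype as PD-L1 knockout and in the other 4 as control, and these are the only groups. PD-L1 is a cell-surface ligand, encoded by Cd274, that restrains immune cells carrying its receptor PD-1. The comparison asks which transcripts of the diseased retina differ when PD-L1 is missing, with microglia, vascular leakage and ERK signalling named in the study's title. The gene counts of the knockout libraries 1 to 4 summed to 34065854, 34543633, 36438248 and 34666089, and those of the control libraries 1 to 4 to 31743404, 32402751, 32760758 and 34054268. Nothing in the labels says that the samples came from separate animals, so the p-values measure only the spread between these samples, which may be technical. How and when the neovascularization was induced, and whether pigment epithelium was kept with the retina, is not given in the sources used here.

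The targeted gene was low in every knockout library. Cd274 (Entrez gene 60533, mm10 chromosome 19, 29362107 to 29388095) held 12, 15, 9 and 11 counts in the 4 knockout libraries and 148, 117, 153 and 165 in the 4 controls. Its level was 0.335 ± 0.0758 CPM (counts scaled to the library size) in the knockout and 4.48 ± 0.544 CPM in the control (SD, n = 4 each; exact two-sided permutation p = 0.0286, the smallest that 70 arrangements allow). The log2 fold change was -3.73 (SE 0.27, edgeR adjusted p = 1.57e-05). All 8 libraries thus carried the Cd274 level that their label implies, with the deleted part of the gene not given in the sources used here. The neighbouring gene Pdcd1lg2 (chromosome 19, 29410919 to 29472927), which encodes PD-L2, the other ligand of PD-1, moved the opposite way. It rose from 0.142 ± 0.203 to 3.02 ± 0.798 CPM (log2 fold change 4.35, SE 0.63, adjusted p = 0.00446), with 144, 86, 114 and 81 counts in the knockout and 2, 2, 0 and 15 in the control. Pdcd1, the gene of their shared receptor, had 2 to 17 counts per library and was too low to test.

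**Figure D1:**
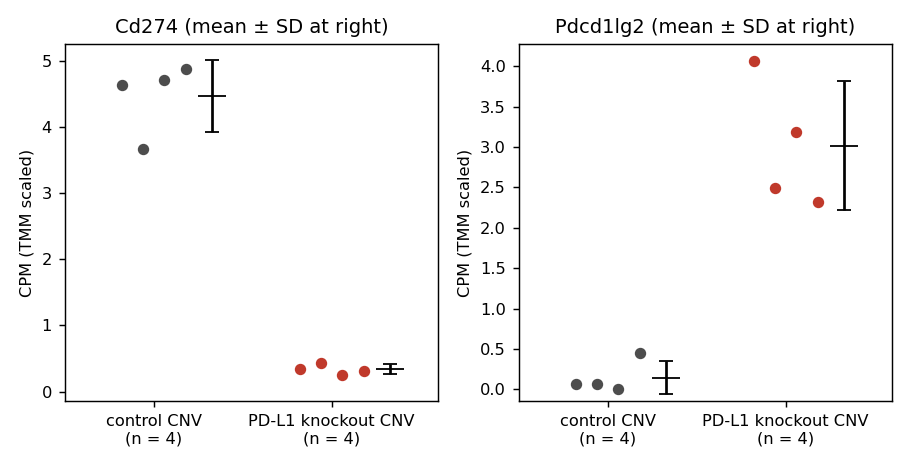
Scaled CPM of Cd274 and Pdcd1lg2 (vertical axes) in each of the 4 control and 4 PD-L1 knockout libraries (points), with the mean ± SD of each group beside them. Cd274 averaged 4.48 CPM in the control and 0.335 CPM in the knockout, while Pdcd1lg2 averaged 0.142 and 3.02 CPM, and the groups did not overlap for either gene.

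Retinas lacking PD-L1 carried more transcript of genes of reactive glia, microglia, complement, antigen presentation and the interferon response, and less of haemoglobin genes. These lists were called with a preset correlation between genes, and none of them passed with an estimated correlation. Rod, cone, bipolar and ganglion cell genes differed little. Of 16861 genes tested, 430 changed: 203 were higher and 227 lower in the knockout (edgeR, adjusted p under 0.05). Most changes were small, and 314 of the 430 were below 1 in absolute log2 fold change; beyond that, 80 genes were higher and 36 lower. The 4 knockout values lay wholly apart from the 4 control values for 410 of the 430, and for 11% of all tested genes, where chance gives 2.86%. At an unadjusted p under 0.05 there were 3596 genes. When only library totals set the scale, 207 were higher and 131 lower, that is 61.2% higher in place of 47.2%.

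Single libraries weighed on these counts. In a principal component plane of the log values, component 1 (31.6% of the variance) placed the knockout libraries between -28.14 and -20.28 and the controls 1, 2 and 3 at 17.67, 45.06 and 39.81, but control 4 at -6.95. Without control 4 the count was 3209 genes, with 1806 higher and 1403 lower, and all 430 genes were among them with the same sign. It was 204 without knockout 2, 108 without knockout 3, 216 without knockout 4, 162 without control 1, 143 without control 2 and 130 without control 3. Lens transcripts were abundant in knockout 3 and controls 2 and 3, and without these 3 libraries 15 genes were left (7 higher, 8 lower; 3 knockouts against 2 controls). Of the 60 named genes past the threshold, 34 stayed past it in all 8 fits that left out 1 library.

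The largest increases were led by Kdm5d (Y chromosome), a histone demethylase gene, at 20.4 ± 6.81 CPM in the knockout and 0.0468 ± 0.0601 CPM in the control (log2 fold change 8.67, adjusted p = 6.64e-07). Its close copy Kdm5c on the X chromosome, with which reads can be shared, had a log2 fold change of 0.01 (SE 0.09), and Kdm5d counts were 3.33% to 6.8% of Kdm5c counts in the knockouts and at most 0.0364% in the controls. Lcn2, a secreted iron-binding protein of acute inflammation, rose by 2.52 on the log2 scale (SE 0.30, adjusted p = 0.00129). Ccdc194 rose by 2.41, Trim30a, an interferon-inducible gene, by 1.95, Slc6a2, the noradrenaline transporter, by 1.82, and Prss56, a serine protease made by Müller glia, by 1.71. Siglec1, C3 and Ly9 rose by 2.09, 1.94 and 1.68, with less margin. Siglec1 lost the call without knockout 1, 3 or 4 or any of controls 1 to 3 (adjusted p up to 0.0993), C3 without knockout 3 or control 2 or 3 (up to 0.0692), and Ly9 without any library but control 4 (up to 0.15).

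Among the decreases, ND3, a mitochondrially encoded subunit of respiratory complex I, fell by 3.14 on the log2 scale (SE 0.25, adjusted p = 3.51e-05), from 33.5 ± 9.90 to 3.80 ± 1.26 CPM. Plac9a fell by 1.69 and Duxbl1 fell by 1.62, neighbours on chromosome 14. Col4a3, a basement membrane collagen, fell by 1.26 (SE 0.12, adjusted p = 0.000198). Hbb-bs, a beta-globin gene, fell by 2.23. Cstdc5 fell by 3.85, but rested on control 2, at 6.32 CPM against 0.493 to 0.69 CPM in the other controls: without it the value was -2.02, and without any library but control 4 the call ended (adjusted p up to 0.142).

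Genes of reactive gliosis, the response of Müller glia and astrocytes to injury, rose together. Of the 17 tested, 11 rose, none fell and 6 did not pass; adjusted over the list alone, 14 rose. A2m, a protease inhibitor, rose by 1.35 (SE 0.13, adjusted p = 0.00015) from 15.8 ± 2.80 to 40.3 ± 3.30 CPM. Cebpd, a transcription factor of the acute-phase response, rose by 1.02 and Osmr, the oncostatin M receptor, by 0.99. Serpina3n, Stat3 and Vim, chosen after their values were seen, rose by 1.6, 0.64 and 0.62. Gfap, the classical filament protein of reactive glia, had a log2 fold change of 0.28 (SE 0.12, adjusted p = 0.208). The median of the list was 0.77 and it was called higher (camera adjusted p = 7.89e-24; adjusted p = 0.073 with an estimated correlation). Markers of Müller glia themselves, such as glutamine synthetase and aquaporin 4, moved little: 1 of 12 rose over all genes and 3 adjusted over the list alone, with a median of 0.17 (camera adjusted p = 0.00503; adjusted p = 0.327 with an estimated correlation). The 1 was Crym, a thyroid hormone-binding protein, which rose by 0.71 (SE 0.11, adjusted p = 0.0073). In the same libraries haemoglobin transcript was lower in all 4 knockouts (1.59 to 4.03 CPM) than in all 4 controls (9.86 to 14.1 CPM).

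**Figure D2:**
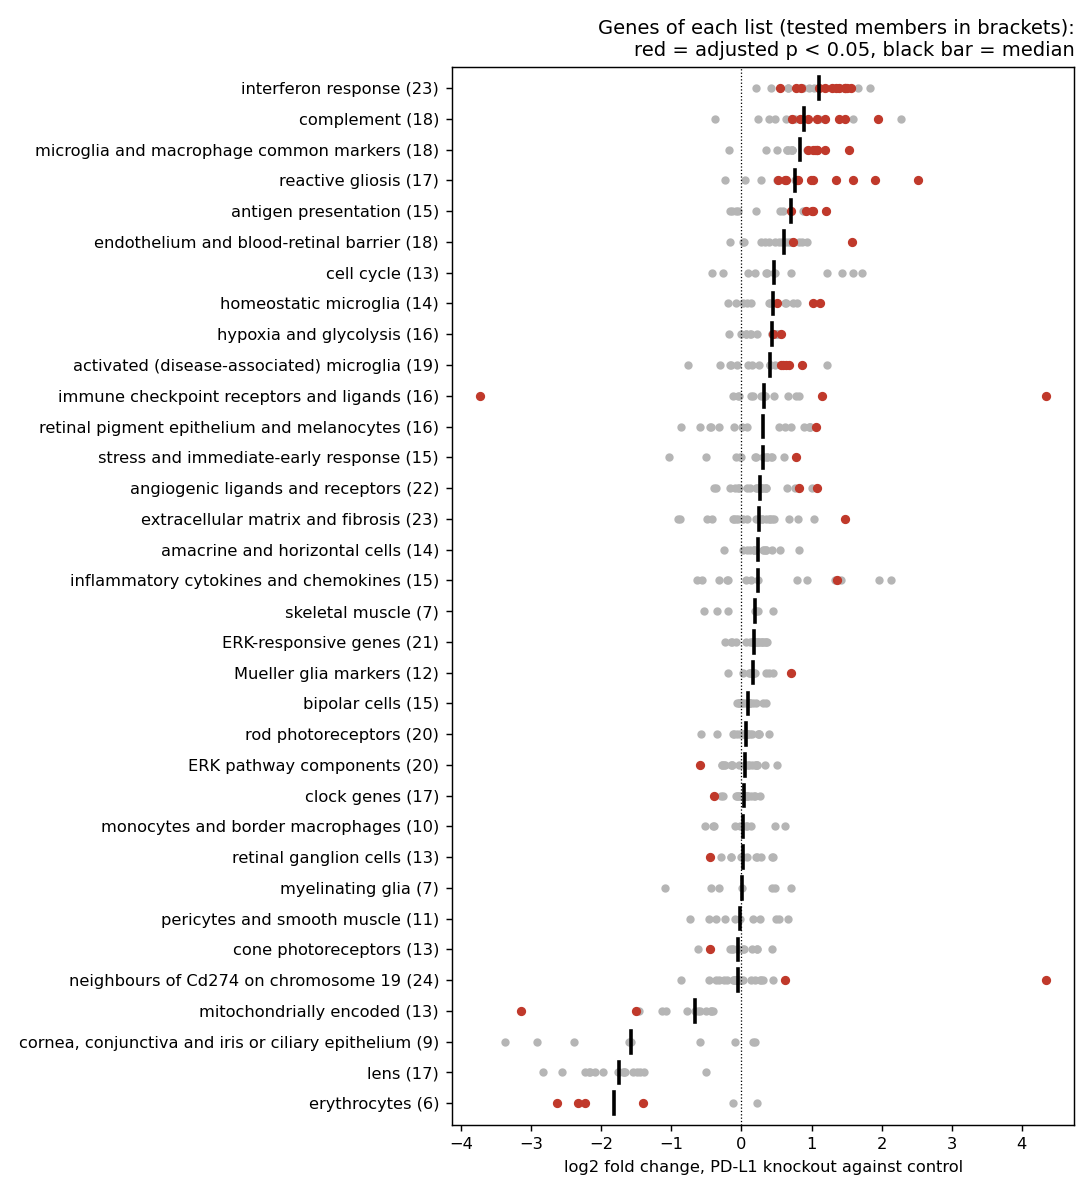
Log2 fold change (horizontal axis, knockout against control) of every tested gene in the 34 lists tested, with the number of tested members in brackets, genes past the adjusted threshold in red and the list median as a black bar. The interferon, complement, microglial and gliosis medians lie at 1.11, 0.89, 0.83 and 0.77, and the erythrocyte and lens medians at -1.82 and -1.75.

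Microglia are the resident macrophages of the retina, and genes common to microglia and macrophages were higher in the knockout. Of 18 tested, 7 rose, none fell and 11 did not pass; adjusted over the list alone, 14 rose. C1qa rose by 1.2 (SE 0.17, adjusted p = 0.00349) from 12.2 ± 3.12 to 27.9 ± 3.59 CPM, Laptm5, a lysosomal protein of blood-derived cells, by 1.08, Csf1r, the receptor microglia need to survive, by 1.03 and C1qb by 0.94. Aif1, which encodes the marker IBA1, had a log2 fold change of 0.51 (SE 0.35, adjusted p = 0.418), and control 4 was the lowest library at 0.74 CPM. The list median was 0.83 (camera adjusted p = 1.54e-17; adjusted p = 0.146 with an estimated correlation).

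Genes of resting and of activated microglia had lower medians. Among 14 homeostatic microglial genes 3 rose (6 adjusted over the list alone), none fell and the median was 0.46 (camera adjusted p = 4.39e-05; adjusted p = 0.183 with an estimated correlation). Olfml3 rose by 1.13 and Cx3cr1, the fractalkine receptor, by 1.02. Cx3cr1 lost the call without knockout 1, 3 or 4 or control 2 or 3 (adjusted p up to 0.0949). P2ry12 and Siglech, chosen after their values were seen, had log2 fold changes of 0.03 (SE 0.20) and 0.13 (SE 0.26). Among 19 genes of activated, disease-associated microglia 5 rose and none fell; adjusted over the list alone, 9 rose and 1 fell. Ctsd and Ctsz, lysosomal proteases, rose by 0.68 and 0.60, the tetraspanin Cd9 by 0.64 and the growth factor Csf1 by 0.87. Csf1 lost the call without knockout 1, 3 or 4 or control 2 or 3 (adjusted p up to 0.122). Members such as Trem2, Itgax and Clec7a were not among the 5. In the control Ctsd, Ctsz, Cd9 and Csf1 averaged 272, 28.7, 44.6 and 5.93 CPM, against 12.2 CPM for C1qa. Counts of whole retina do not show which cells a transcript came from. The rise of these genes therefore cannot be assigned to activated microglia. The list median was 0.41 (camera adjusted p = 6.45e-06; adjusted p = 0.2 with an estimated correlation).

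Genes of complement, the plasma cascade that tags targets for removal, were higher as a list. Of 18 genes, 8 rose, none fell and 10 did not pass; adjusted over the list alone, 13 rose and 1 fell. Serping1, the C1 inhibitor, rose by 1.48 (SE 0.17, adjusted p = 0.00113) from 12.9 ± 2.39 to 36 ± 7.77 CPM, and C4b by 1.40. The microglial C1qa and C1qb belong to this list as well. The median was 0.89 (camera adjusted p = 5.11e-17; adjusted p = 0.0784 with an estimated correlation). Of 15 antigen presentation genes 5 rose, none fell, and 9 rose adjusted over the list alone. H2-K1 rose by 1.21 (SE 0.14, adjusted p = 0.000901), H2-D1 by 1.01, B2m, the class I light chain, by 1.02 and the peptide transporter Tap2 by 0.70. H2-K1 and H2-D1 belong to a family of similar genes whose reads can be shared. Tap2 lost the call without knockout 1, 3 or 4 or control 1 or 2 (adjusted p up to 0.0887). Class II genes, chosen after their values were seen, had log2 fold changes of -0.05 for H2-Aa (SE 0.29), -0.07 for H2-Eb1 (SE 0.34) and -0.17 for Cd74 (SE 0.29). The median of the list was 0.70 (camera adjusted p = 1.41e-10; adjusted p = 0.101 with an estimated correlation).

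**Figure D3:**
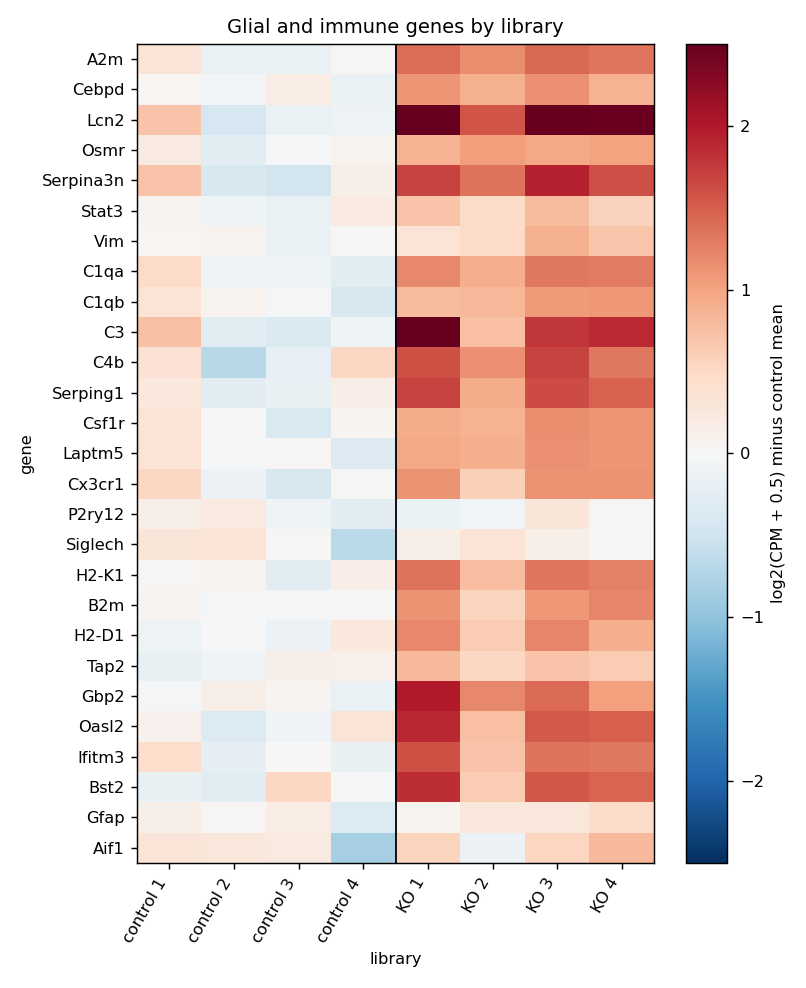
Glial and immune genes (vertical axis) in each library (horizontal axis), coloured by log2(CPM + 0.5) minus the control mean of the gene. A2m, C1qa, Serping1, H2-K1 and Gbp2 were higher in all 4 knockout libraries, by 1.35, 1.2, 1.48, 1.21 and 1.5 in the fitted log2 fold change, whereas P2ry12 was at 0.03.

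The interferon response had the highest median of the lists tested, 1.11. Of its 23 genes, 12 rose, none fell and all 23 had positive log2 fold changes; adjusted over the list alone, 22 rose (camera adjusted p = 7.07e-24; adjusted p = 0.159 with an estimated correlation). Gbp2, a guanylate-binding protein, rose by 1.5 (SE 0.19, adjusted p = 0.002) from 8.79 ± 0.870 to 24.9 ± 7.89 CPM. Bst2, which tethers virus particles, rose by 1.47, Oasl2 by 1.47 and Ifitm3 by 1.29. Knockout 2 was the lowest knockout library for Oasl2, Ifitm3 and Bst2, at 40.1, 17.7 and 9.59 CPM, still above every control. Inflammatory cytokines and chemokines changed in few cases. Of 15 tested, 1 rose, the adhesion molecule Icam1 (log2 fold change 1.36, adjusted p = 0.0391), and 4 rose adjusted over the list alone; the median was 0.24 (camera adjusted p = 0.0082; adjusted p = 0.299 with an estimated correlation). Ccl2 had a log2 fold change of 0.79 (SE 0.38, adjusted p = 0.249) at 0.640 ± 0.0341 against 0.369 ± 0.0988 CPM, and Il1b of -0.63 (SE 0.51, adjusted p = 0.486). Tnf, with 0 to 8 counts per library, was too low to test, and Il6 was not analysed here. The cytokine list lost its call without control 4 (adjusted p = 0.129), and Icam1 without any library but control 4 (up to 0.142).

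Among immune checkpoint genes the targeted ligand fell and its relative rose. Cd274 and Pdcd1lg2 are neighbours on chromosome 19. A local effect of the targeted allele on Pdcd1lg2 cannot be told apart from a response to the loss of PD-L1. Of 16 tested, Pdcd1lg2 and Lgals9 rose, Cd274 fell and 13 did not pass, with the same 3 adjusted over the list alone. Lgals9, the galectin that binds the receptor TIM-3, rose by 1.15 (SE 0.21, adjusted p = 0.0139), a call that ended without knockout 3 or control 3 (adjusted p up to 0.0645). The median was 0.32 (camera adjusted p = 0.0231; adjusted p = 0.282 with an estimated correlation), and without knockout 1 the list missed the threshold (adjusted p = 0.0628).

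Transcripts of ERK pathway components did not shift in 1 direction as a list. Of 20 pathway components 1 fell over all genes, and adjusted over the list alone 2 rose and 4 fell. Mapk3, which encodes the kinase ERK1, had a log2 fold change of 0.20 (SE 0.10, adjusted p = 0.237). The list was not called (median 0.06, camera adjusted p = 0.96), with the mean at 0.00 and the test pointing down. Genes that ERK activity induces had a median of 0.18, and none of 21 passed over all genes while 1 rose adjusted over the list alone. Junb and Dusp6, a phosphatase induced by ERK and acting on it, had values of 0.37 (adjusted p = 0.0574) and 0.33 (adjusted p = 0.181), and Junb passed without control 4 (adjusted p = 0.0234). The list was called higher (camera adjusted p = 0.0312; adjusted p = 0.299 with an estimated correlation), a call that ended without knockout 2 or 4 or control 2 or 4 (adjusted p up to 0.103). Phosphorylation, by which ERK is activated, is not measured by transcript counts.

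Angiogenic ligands and receptors changed in 2 of 22 genes. Fgf2, a fibroblast growth factor, rose by 0.83 (SE 0.16, adjusted p = 0.0207) from 76.8 ± 7.79 to 136 ± 37.0 CPM, and Thbs1, an inhibitor of vessel growth, by 1.07 (SE 0.25, adjusted p = 0.045). Adjusted over the list alone, 2 rose as well. Vegfa, the main driver of neovascularization, was at 192 ± 12.4 CPM in the knockout and 204 ± 20.4 CPM in the control (log2 fold change -0.09, SE 0.09, adjusted p = 0.615). The list median was 0.26 (camera adjusted p = 0.00708; adjusted p = 0.274 with an estimated correlation). Fgf2 lost the call without knockout 3 or 4 or any of controls 1 to 3 (adjusted p up to 0.0746), and Thbs1 without knockout 2, 3 or 4 or control 2 or 3 (up to 0.137).

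Genes of endothelium and the blood-retinal barrier leaned higher. Of 18 tested, 2 rose, none fell and 17 were positive; adjusted over the list alone, 8 rose, and the median was 0.61 (camera adjusted p = 2.22e-06; adjusted p = 0.183 with an estimated correlation). Vwf, the clotting factor stored in endothelium, rose by 1.58 and F11r, a junctional adhesion molecule, by 0.74. Both lost the call without any library but control 4 (adjusted p up to 0.16 for Vwf and 0.11 for F11r), and control 4, at 4.53 CPM of Vwf, stood above the other controls at 1.48 to 1.66 CPM. Pericyte and smooth muscle genes were not called (11 tested, none changed by either adjustment, median -0.01, camera adjusted p = 0.996); Rgs5 was at -0.23 (adjusted p = 0.163) and Cspg4 at 0.67 (adjusted p = 0.289). Of 23 matrix and fibrosis genes 1 rose by either adjustment, the protease inhibitor Timp1 (log2 fold change 1.48, SE 0.28, adjusted p = 0.0182). The list median was 0.25 (camera adjusted p = 0.0231; adjusted p = 0.398 with an estimated correlation). The matrix call ended without knockout 1 or 3 or control 3 or 4 (adjusted p up to 0.105), and that of Timp1 without knockout 3 or control 1 or 3 (up to 0.0799). Hypoxia and glycolysis genes had a median of 0.44: 2 of 16 rose, the lactate transporter Slc16a3 by 0.57 and Pgk1 by 0.45, and 8 rose adjusted over the list alone (camera adjusted p = 3.62e-05; adjusted p = 0.203 with an estimated correlation). Slc16a3 and Pgk1 lost the call without knockout 2, 3 or 4 or any of controls 1 to 3 (up to 0.124 and 0.15).

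Photoreceptor and inner retinal neuron genes changed in few cases. None of 20 rod genes passed by either adjustment (median 0.06, camera adjusted p = 0.723), with Rp1 at -0.34 (adjusted p = 0.109) and Sag, rod arrestin, at 0.39 (adjusted p = 0.126). Of 13 cone genes Arr3, cone arrestin, fell by 0.45 (adjusted p = 0.0375); adjusted over the list alone 1 rose and 2 fell (median -0.05, camera adjusted p = 0.877). Of 13 ganglion cell genes Nefl, a neurofilament subunit, fell by 0.45 (adjusted p = 0.0351), alone by either adjustment (median 0.02, camera adjusted p = 0.832). None of 15 bipolar cell genes passed by either adjustment (median 0.09, camera adjusted p = 0.131), with Scgn at 0.31 (adjusted p = 0.111). Amacrine and horizontal cell genes were called higher as a list (14 tested, none over all genes and 1 adjusted over the list alone, median 0.24, camera adjusted p = 0.00629; adjusted p = 0.546 with an estimated correlation), with Septin4 at 0.35 (adjusted p = 0.0568) and Slc6a9, a glycine transporter, at 0.43 (adjusted p = 0.125). Arr3 lost the call without knockout 1, 3 or 4 or any of controls 1 to 3 (adjusted p up to 0.139), and Nefl without any library but control 4 (up to 0.107). Without control 4, where the ganglion list summed to 1240 CPM against 826 to 1003 CPM in the other controls, that list was called higher (adjusted p = 0.00254) and Rp1, Sag, Scgn, Septin4 and Slc6a9 passed (adjusted p = 0.0274, 0.0116, 0.0345, 0.00608 and 0.000807), while without knockout 3 the bipolar list did (adjusted p = 0.0414).

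Transcripts of other tissues differed between single libraries and between the groups. The lens list, mostly crystallins, summed to 2822 CPM in knockout 3, 6824 in control 2 and 1927 in control 3, and to between 4.66 and 51.4 CPM in the other 5 libraries. It was called lower as a list (17 genes, none past the threshold by either adjustment, median -1.75, camera adjusted p = 0.00556; adjusted p = 0.635 with an estimated correlation), but not without knockout 1 (adjusted p = 0.0671) or control 2 (adjusted p = 0.308). Cryge and Crygf, near-identical copies, were at -2.83 (SE 1.63) and -2.56 (SE 1.59), and at 0.68 and 0.59 without control 2. Genes of cornea, conjunctiva and iris or ciliary epithelium were called lower (9 tested, none over all genes and 4 lower adjusted over the list alone, median -1.58, camera adjusted p = 0.0139; adjusted p = 0.454 with an estimated correlation), again not without knockout 1 (adjusted p = 0.0671) or control 2 (adjusted p = 0.093). Krt12 was at -1.61 (adjusted p = 0.058) and Krt5 at -2.38 (adjusted p = 0.101), and Krt12 passed without knockout 3 (adjusted p = 0.0287) or control 4 (adjusted p = 0.00926), as did Krt5 without control 4 (adjusted p = 0.0193).

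Pigment epithelium genes summed to 208, 390, 384 and 399 CPM in knockouts 1 to 4 and to 342, 287, 202 and 145 CPM in controls 1 to 4. The list was called higher (16 genes, 1 rose over all genes and 5 adjusted over the list alone, median 0.31, camera adjusted p = 0.0167; adjusted p = 0.546 with an estimated correlation), but not without knockout 4, control 3 or control 4 (adjusted p up to 0.348). The 1 gene was Rgr, a retinal opsin of pigment epithelium and Müller glia (log2 fold change 1.06, adjusted p = 0.0444), which lost the call without knockout 2, 3 or 4 or any of controls 1 to 3 (up to 0.139).

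Erythrocyte genes fell: 4 of 6, all haemoglobin, with 1 higher and 4 lower adjusted over the list alone (median -1.82, camera adjusted p = 2.22e-06; adjusted p = 0.0784 with an estimated correlation). Hbb-bs fell by 2.23 (SE 0.29, adjusted p = 0.00238), from 8.67 ± 1.53 to 1.84 ± 0.802 CPM. Hba-a2 fell by 2.62, Hbb-bt fell by 2.33 and Hba-a1 fell by 1.40, with reads that can be shared within the pairs Hba-a1 and Hba-a2, and Hbb-bs and Hbb-bt. Without 1 library, Hba-a2 lost the call in all cases but knockout 4 and control 4 (adjusted p up to 0.119), Hbb-bt in all but knockout 1 and control 4 (up to 0.122) and Hba-a1 in all but control 4 (up to 0.137). All 13 mitochondrially encoded genes had negative log2 fold changes, of which 2 fell over all genes and 8 adjusted over the list alone (median -0.67, camera adjusted p = 1.41e-10; adjusted p = 0.183 with an estimated correlation). Besides ND3, ATP6 fell by 1.51 (adjusted p = 0.0381), a call lost without any library but control 4 (up to 0.108). These genes took 3.27% to 5.07% of the counts in the knockouts, 6.03% to 7.00% in controls 1 to 3 and 3.57% in control 4.

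**Figure D4:**
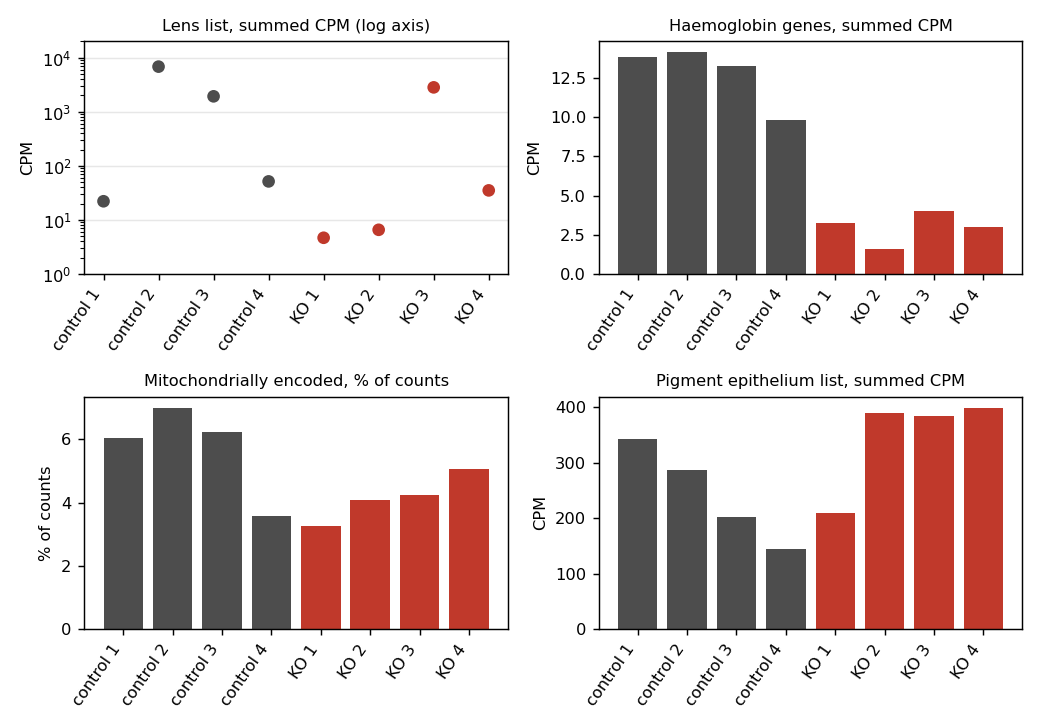
Summed CPM of the lens list on a log axis (points), and summed CPM of the haemoglobin genes, percent of counts on mitochondrially encoded genes and summed CPM of the pigment epithelium list (bars from 0), for each of the 8 libraries on the horizontal axes. Lens transcript reached 2822, 6824 and 1927 CPM in knockout 3, control 2 and control 3, and haemoglobin was 1.59 to 4.03 CPM in the knockouts against 9.86 to 14.1 CPM in the controls.

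Genes of blood-derived immune cells were tested in small numbers. Among 10 genes of monocytes and border macrophages none passed by either adjustment (median 0.02, camera adjusted p = 0.96); Fn1, fibronectin, was at 0.47 (adjusted p = 0.138, and 0.00805 without control 4) and S100a4 at -0.39 (adjusted p = 0.455). Only 1 lymphocyte gene, Lck at 0.33 (adjusted p = 0.671), and 3 neutrophil genes could be tested, too few for a list test; of the latter Lcn2 rose over all genes and 2 rose adjusted over the list alone, and Lcn2 belongs to the gliosis list too. Skeletal muscle genes (7 tested, none changed by either adjustment, median 0.19) and myelin genes (7 tested, none over all genes and 1 higher adjusted over the list alone, median 0.01) were not called (camera adjusted p = 0.96 each). Pvalb was at -0.35 (adjusted p = 0.209), Acta1 at 0.45 (adjusted p = 0.283) and Pmp22 at 0.44 (adjusted p = 0.09), and without control 4 Pvalb and Pmp22 passed (adjusted p = 0.0229 and 0.0282). Stress genes had a median of 0.30 with 1 of 15 higher, Gadd45b by 0.78, and 5 higher adjusted over the list alone (camera adjusted p = 0.008; adjusted p = 0.183 with an estimated correlation). Of 17 clock genes Nr1d2 fell by 0.40, alone by either adjustment (median 0.03, camera adjusted p = 0.96). None of 13 cell cycle genes passed over all genes, and 3 rose and 1 fell adjusted over the list alone (median 0.47, camera adjusted p = 0.00758; adjusted p = 0.146 with an estimated correlation). Mki67, a proliferation marker, was at 1.23 (SE 0.33, adjusted p = 0.0652, and 0.035 without control 4). Gadd45b lost the call without knockout 1 or 3 or any of controls 1 to 3 (adjusted p up to 0.117), and Nr1d2 without knockout 1, 2 or 3 or any of controls 1 to 3 (up to 0.106).

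Genes around Cd274 on chromosome 19 can be carried along with a targeted allele. Of 24 in the list fixed for this, which includes Kdm4c from chromosome 4, Pdcd1lg2 and Slc1a1, a glutamate transporter, rose over all genes, and 3 rose and 3 fell adjusted over the list alone. Slc1a1 rose by 0.62 (adjusted p = 0.0444) and lost the call without any library but control 4 (adjusted p up to 0.155). The list was not called (median -0.05, camera adjusted p = 0.96), with a mean of 0.15 and a test pointing up. The median, mean and test also differed in sign for ERK components, monocytes, pericytes, myelin, muscle and clock genes, none of which was called. Of the 34 lists tested, 19 were called higher and 4 lower with the preset correlation, and with an estimated correlation none passed, although 8 had an unadjusted p under 0.05; fry, which asks only whether the genes of a list move one way on balance, called 12.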

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

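The corrections for lens transcript and for GC content and length, and the comparison of the microglial lists, were chosen only after the results were seen. Of the 35 ways to split the 8 libraries into 4 and 4, the real split gave the most changed genes, 430. The highest of the others gave 1. Those splits mix knockouts with controls, so a difference between the groups widens their spread and lowers their counts. First of 35 is the most extreme place this design allows, so chance differences between samples cannot be excluded. A library was singled out where its gap to the nearest of its group, over the range of the group, passed Dixon's limit. Chance does this in about 1 in 20 groups. It happened in 17 of 204 groups, where 10.2 would be picked out by chance, with 5 of the 17 in knockout 3, 4 in control 4 and 3 in control 2.

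Lens transcript summed to 2820 CPM in knockout 3 against 4.66 to 35.1 CPM in the other knockouts. Of its crystallin genes, Cryge stood at 19.8 CPM in knockout 3 (others 0.0283 to 0.629) and 137 CPM in control 2 (others 0.0627 to 9.12), and Crygf at 15.1 CPM (others 0 to 0.315) and 83.8 CPM (others 0.125 to 7.49). The corneal keratin Krt12 was highest in knockout 3 as well, at 1.57 CPM against 0.435 to 0.6 CPM, and Vegfa lowest there, at 174 CPM against 196 to 200 CPM. In knockout 1 the pigment epithelium list summed to 208 CPM, against 384 to 399 CPM, and the ganglion cell list to 863 CPM, against 961 to 967 CPM. In knockout 2 Cx3cr1 was at 9.16 CPM, against 13.3 to 13.4 CPM. Control 4 held 0.444 CPM of Pdcd1lg2 (others 0 to 0.0628), 0.74 CPM of Aif1 (others 2.09 to 2.26), 4.53 CPM of Vwf (others 1.48 to 1.66) and 50.7 CPM of Crym (others 66.5 to 69.2). Control 1 held 61.6 CPM of Mapk3 (others 72.4 to 73.9), control 2 held 6.32 CPM of Cstdc5 (others 0.493 to 0.69) and control 3 held 45.6 CPM of Scgn (others 58 to 59.4).

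The microglial, complement, antigen presentation, interferon and gliosis lists were all higher in the knockout with a preset correlation, and none of the 5 passed with an estimated correlation (adjusted p = 0.146, 0.0784, 0.101, 0.159 and 0.073). More microglia alone would raise homeostatic genes as much as the genes common to microglia and macrophages, but the homeostatic median lay lower (difference -0.375, one-sided permutation of genes, which are not independent replicates, p = 0.0051). The homeostatic members were spread widely, and 12 of 14 were positive. Olfml3 and Cx3cr1, at 1.13 and 1.02, lay above the common median of 0.83, while P2ry12, Siglech and Gpr34, chosen after their values were seen, were at 0.03 (SE 0.20), 0.13 (SE 0.26) and -0.08 (SE 0.23). Several homeostatic genes (such as Tgfbr1 and Mertk) are also expressed by other retinal cells, which can lower their median. The lower median thus argues only against more cells in an unchanged state as the whole source, and more cells in a changed state stay possible. With the preset correlation, 5 of the 5 lists stayed higher after removal of each library's trend with GC content and length and 5 with the lens covariate, which argues against GC content or gene length bias and against lens tissue carried into single libraries as the whole cause. An altered state of glia and microglia linked to the genotype may be a source of the pattern, as a hypothesis found and tested on the same data, while a difference between the groups in lesion extent or genetic background stays open and untested.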

How the results depend on the processing

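The settings without the 3 libraries rich in lens transcript, with the lens covariate, with the GC content and length correction, with that correction and the replicate block, and with scaling without mitochondrial genes were chosen only after the results were seen. Cd274 was lower and past the threshold in every setting that tested it, at -3.88 to -3.61 in all fits of counts, -0.94 on log2(FPKM + 1) and -2.70 on log2(FPKM + 0.1), where a pseudocount shrinks the difference by construction. The lists of microglia and macrophages, homeostatic and activated microglia, interferon response, antigen presentation, complement, gliosis, endothelium, stress and hypoxia stayed higher, and erythrocytes lower, and past the threshold in every setting that tested lists but the estimated correlation. Of the 60 named genes past the threshold none turned its direction in any setting, and all 60 kept their side with RLE factors, upper quartile scaling and scaling without mitochondrial genes. Calls lost among them were 2 with library size only, 4 with robust dispersions, 1 with limma-voom, 13 on log2(FPKM + 1), 10 on log2(FPKM + 0.1), 1 with protein-coding genes, 24 with glmTreat, 15 with the lens covariate, 7 with the GC correction and 53 without the 3 libraries.

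The counts of changed genes (430; 203 higher, 227 lower) went to 690 (336 and 354) without a filter, where more genes were tested, 1320 (596 and 724) with DESeq2 and 2731 (1456 and 1275) with sample quality weights. They went to 228 in total and 78 lower on log2(FPKM + 1), 103 lower on log2(FPKM + 0.1), 131 lower with library size only, 264 (128 and 136) with the lens covariate, 97 (66 and 31) with glmTreat, which asks for a fold beyond 1.2, and 15 (7 and 8) without the 3 libraries, with fewer samples. These settings also differ in the numbers of genes and samples and the fold limit, and the cause of the changed counts was not tested. RLE factors, upper quartile scaling, the stricter filter, robust dispersions, protein-coding genes, limma-voom, the fit without genes within 20 Mb, the GC correction and scaling without mitochondrial genes stayed within 1.5 times of every count. Without 1 library the counts ranged from 108 to 3209 in total, 62 to 1806 higher and 46 to 1403 lower. All of these fits had fewer samples, also the one without control 4 that gave 3209, and the cause was not tested. No scaling moved the median log2 fold change of all genes by more than 0.1. Among the 203 higher genes 195 stayed higher with library size only, 201 with DESeq2 and 153 with the GC correction, and among the 227 lower genes 131, 218 and 107 stayed lower.

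Whether the numbers in the titles pair the libraries is not known. Deviations of same-numbered libraries from their group means correlated at 0.255, -0.0585, 0.174 and -0.00109 for numbers 1 to 4. Not every library correlated best with its own number, although knockout 1 did. Weak correlations of this kind cannot exclude a pairing. With the replicate block 228 genes were called (121 higher, 107 lower), and with the GC correction and the block 265 (120 lower). Of the 60 calls of named genes 17 and 15 ended in these fits, and of the 23 list calls 0 and 1.

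List calls (19 higher, 4 lower) went to 0 and 0 with an estimated correlation, 11 and 1 with fry and 2 lower with the lens covariate, and ranged from 2 to 4 lower without 1 library; the cause was not tested. DESeq2, glmTreat and the fit without genes within 20 Mb gave no list tests, the last of these no value for Cd274, and the stricter filter gave values for 77 of 88 named genes and 32 of 34 lists, DESeq2 for 81 of 88 genes.

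No called list turned its direction. Lists not called did so, at adjusted p above 0.05 wherever they turned, and the cause was not tested. Pericytes turned with upper quartile scaling (0.986), library size only (0.969), no filter (0.985), the stricter filter (0.924), protein-coding genes (0.937), limma-voom (0.972), weights (0.987), log2(FPKM + 1) (0.755), log2(FPKM + 0.1) (0.987), without the 3 libraries (0.66), with the lens covariate (0.956), and with the GC correction without and with the block (0.997 each). ERK components turned with library size only (0.969), weights (0.879), log2(FPKM + 1) (0.923) and log2(FPKM + 0.1) (0.965). Neighbours of Cd274 turned with protein-coding genes (0.937), limma-voom (0.891), weights (0.783), log2(FPKM + 1) (0.755), log2(FPKM + 0.1) (0.965), without the 3 libraries (0.716), and in the list test without called genes near Cd274 (0.364). Clock genes turned with weights (0.813), log2(FPKM + 1) (0.927) and log2(FPKM + 0.1) (0.965), and muscle with log2(FPKM + 1) (0.869), log2(FPKM + 0.1) (0.939) and the lens covariate (0.902). Monocytes turned with weights (0.783) and without the 3 libraries (0.559), myelin with protein-coding genes (0.965) and without the 3 libraries (0.845), ganglion cells without the 3 libraries (0.092) and with the GC correction (0.874), and cones with the lens covariate (0.907). Lists that turned without 1 library had adjusted p over the 8 such fits of 0.811 to 0.972 for pericytes, 0.811 to 0.978 for ERK components, 0.672 to 0.955 for the neighbours, 0.583 to 0.974 for clock genes, 0.759 to 0.969 for muscle, 0.27 to 0.972 for monocytes, 0.442 to 0.978 for myelin, 0.00254 (without control 4, where the list kept its direction) to 0.949 for ganglion cells, 0.37 to 0.966 for cones and 0.173 to 0.945 for rods. Of the genes, without 1 library Cryge ranged from -7.30 to 0.68 and Crygf from -7.72 to 0.59, the positive values without control 2, which held most of their counts.

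Depth limits the genes of few counts: with 0.028 to 0.0314 CPM per count, levels near 0.1 CPM rest on few reads, and Pdcd1 and Tnf could not be tested.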

Other observations

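The enrichment test, the definition of the genes with the widest differences and the tests of Kdm5d were chosen only after the results were seen, as was the GC content and length correction. Of the 203 higher genes 196 were annotated. They held 43 of the 388 tested genes of the Gene Ontology term immune system process (adjusted p = 9.87e-25). They also held 11 of 41 of the cellular response to interferon-beta (adjusted p = 1.93e-09). The enrichment test takes genes as independent, so its p-values leave out that such genes can move together. Of the 11 genes of the MHC class I protein complex 6 rose, of which 3 are in the fixed list. Of the others, H2-T23 rose by 1.39 (SE 0.18, adjusted p = 0.00247) and H2-Q4 by 0.97 (SE 0.16, adjusted p = 0.00952), whose reads can be shared with relatives. H2-Q7, also among them, rose by 3.49 (SE 0.63, edgeR adjusted p = 0.014). It was near absent in the control, at 0.038 CPM against 0.47 CPM in the knockout, levels that rest on few reads. The 227 lower genes passed for none of 3896 Gene Ontology terms, the closest being centriole, with 9 of 124 (adjusted p = 0.153, unadjusted p = 3.92e-05). In KEGG, 16 of 376 genes of herpes simplex virus 1 infection were lower (adjusted p = 0.000146). Most of the 16 encode zinc-finger proteins, such as Zfp946, which fell by 0.68, and Zfp950, which fell by 0.57, and these regulate transcription in uninfected cells. African trypanosomiasis and malaria passed as well (hypergeometric adjusted p = 0.011 and 0.0313), each through the same 4 haemoglobin genes. The enrichment of the lower genes was not repeated after the GC content and length correction.

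Several single genes, chosen after their values were seen, separated the groups cleanly. The genetic background of the groups is not given in the sources used here. For these genes a difference in background therefore cannot be told apart from the loss of PD-L1. The same holds for the differences in the gliosis, microglial, complement, antigen presentation and interferon lists. Crb1, which encodes a protein of the junctions between photoreceptors and Müller glia (chromosome 1, 139176649 to 139379316), fell by 1.21 (SE 0.09, adjusted p = 1.57e-05), from 455 to 196 CPM. Wdfy1, an endosomal adaptor of innate signalling, rose by 1.23 (SE 0.11, adjusted p = 6.35e-05). Col4a3 and its neighbour Col4a4 on chromosome 1, both of the basement membrane, were at -1.26 (SE 0.12) and -0.83 (SE 0.14). Plac9a, Tmem254a and Duxbl1, which lie together on chromosome 14 between 25888403 and 25990166, had log2 fold changes of -1.69, -1.19 and -1.62. Of the sex-linked genes, Xist was read at 2732 to 5152 CPM in all 8 libraries and Eif2s3y at 0.188 CPM at most; Ddx3y and Uty were not analysed here.

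The widest differences were in 14 genes past the threshold, with no overlap and an absolute log2 fold change of at least 3, some of them read in both genotypes. Gm15446 (chromosome 5) had 9.89 CPM in the control and 0.0142 in the knockout, Gm35279 (chromosome 13) 0.0314 and 5.62, and Kdm5d 0.0468 and 20.4. Of the 14, 9 lie on chromosomes other than 19, while LOC118567500 and LOC118568080 have no known position. The 9 are not all separate places, as some lie side by side, ND3 is mitochondrially encoded and Cstdc5 rested on control 2. The rule for this count was set after the genes were seen. The 9 argue only against a segment linked to the knockout allele on chromosome 19 alone as the whole source. For Kdm5d, the highest ratio of Eif2s3y to Kdm5d counts in the knockouts was 0.00173, which argues against cells with a Y chromosome, and the lowest knockout ratio to Kdm5c exceeded the highest control ratio 91.5 times (3.33% to 6.8% against at most 0.0364%), which argues against reads shared at a constant rate, with Kdm5c itself at 0.01 (SE 0.09). A different genetic background of the groups may be a source but cannot be told apart. The 19 neighbouring pairs among the genes with the smallest p lay above the median of the other splits, 13, and below their highest, 26. Among the 14, Gm15446 lies within LOC115490200 on chromosome 5, which went from 57.1 CPM in the control to 0.398 in the knockout. Gm16867 and Gm27177 (chromosome 14, starts 69363290 and 69581540) had 0 CPM in the knockout and 0.86 and 0.54 in the control. Reads of overlapping genes cannot be told apart, and these positions, seen after the fact, were not tested.

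Near Cd274, 13 of 303 genes within 20 Mb changed against 417 of 16558 elsewhere (odds ratio 1.74, 95% interval 0.905 to 3.05, Fisher's exact two-sided p = 0.0631). An interval that includes 1 had been set beforehand as the result that would exclude a linked segment from another strain. That bound was wrong, since this interval also includes odds above 1 and so excludes nothing. Within 1 Mb, 3 of 23 tested genes changed: Cd274 itself, whose call the genotype implies, Pdcd1lg2 and Slc1a1. The 13 also include Ifit1, Ifit3 and Ifit3b, which are interferon-induced, so the odds ratio counts genes that need no such segment. Another of the 13 is Gm41844 (start 38379292), with a log2 fold change of 6.23. It had 0.852 CPM in the knockout and 0.0077 CPM in the control. Whether a linked segment contributes stays open.

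Genes lower in the knockout had less GC and longer models: a median GC content of 41% and length of 5798 bases, against 52% and 3140 for the higher genes and 49.7% and 3670 for genes not called. After removal of each library's trend with GC content and length, a share of 0.471 of the lower genes stayed past the threshold, against 0.754 of the higher. In all, 171 genes were lower after it, of which 107 were among the 227. The median log2 fold change of the lower genes went from -0.53 to -0.41 and their median SE from 0.109 to 0.102, and 227 of 227 kept their sign. Why single calls ended was not tested, and scaling by library size only also left 131 of the 227. GC content or gene length bias is a candidate source of part of the decreases, while a difference linked to the genotype stays open for the rest.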
